A study of Escherichia coli K-12 with 2 samples.

How the data were processed

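The series measured where RpoS bound the chromosome of Escherichia coli K-12 MG1655 by ChIP-exo. In this assay protein-bound DNA is cross-linked, precipitated with an antibody and trimmed by an exonuclease up to the bound protein before sequencing, so that binding sites are narrow. Per the labels' protocols, wild-type cells were grown at 37 °C in 100 ml of M9 minimal medium with 0.2% glucose to an OD600 of about 0.6, and chromatin was precipitated with an antibody against RpoS. The labels give 1 group with 2 biological replicates and no control group, mock precipitation or second condition.

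Reads were processed with Bowtie 1.0.0, per the submitters' processing notes. The 1 deposited table lists binding sites on the sequence NC_000913.3, per the file headers, each with a start, an end and a binding intensity. The binding intensity is a signal-to-noise ratio (S/N) that the authors computed for each site, per the file headers. The peak caller, its threshold, the way signal and noise were measured, and whether and at which step the replicates were combined are not given in the sources used here. The table has 1 value per site and no column for a replicate. Agreement between the replicates, a spread between them and values without either of them could therefore not be computed, and no value in the text carries a replicate error. Read depth per sample is unknown from the table. Intervals on shares of sites are Wilson 95% intervals and cover only the counting of listed sites.

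Each S/N was used as deposited to describe and rank sites within this list, and tests on it used log2(S/N) with no pseudocount, since all values were above 0. Genes came from a RefSeq gene table for the same sequence, which gave the start, end, type and symbol of 4651 genes but not their strand. A site was placed by its centre, and lay between genes when the centre was outside every gene. The share of sites between genes was compared with 10000 rotations of the whole site set around the chromosome, which keep the number and spacing of the sites. The smallest shift of 5000 bp was set after a first run had shown that near-zero shifts return almost the observed positions. The smallest two-sided p that these rotations can give is 0.0002.

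Before the data were examined, 15 gene lists were fixed from general knowledge of E. coli. They were known RpoS-dependent genes, osmotic stress and trehalose, acid resistance, oxidative stress and DNA protection, curli with biofilm and morphology, late carbon metabolism, glycolysis with growth-phase carbon metabolism, amino acid biosynthesis, ribosomal proteins, rRNA operons, heat shock (RpoH), envelope stress (RpoE), flagella and chemotaxis (FliA), nitrogen (RpoN), and RNA polymerase with sigma factors and RpoS control. All 365 distinct listed genes were found in the gene table, with 3 names matched through an older symbol. Some lists share members, and the known RpoS-dependent list shares 12 genes with the osmotic list, 11 with the late carbon list, 10 with the acid list, 5 with the oxidative list, 5 with the curli list and 1 with the RpoS control list. A gene counted as having a site when a site centre lay from 300 bp outside to 100 bp inside either of its ends. The plan fixed earlier used a window around the start codon. Without strand the start codon is not known, so the same window was placed at both ends, which also counts sites past the 3′ ends of genes and sites at neighbouring promoters. Under this rule 500 sites were assigned to 1 gene, 1769 to 2 or more genes and 672 to none.

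List members with a site were compared with all other genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 15 lists. As an alternative, the share of members with a site minus that of other genes was compared with the same difference over the 10000 rotations. This took the place of an earlier version, chosen after the data were seen, that set the count of members against rotations alone and passed 10 lists. That version does not compare lists with other genes, since 59.6% of all genes had a site against a mean of 37.6% over rotations. The S/N of sites at list members was compared with that of all other sites by the difference in median log2(S/N), with a two-sided permutation test of 100000 resamples, a bootstrap 95% interval from 2000 resamples, and Benjamini-Hochberg adjustment over the lists with 3 or more sites. Complete enumeration was not feasible even for the smallest list. The smallest p that these permutations can give is 1e-05. Sites and genes are not replicates, neighbouring genes can share a site, and the p-values describe this 1 list of sites rather than variation between cultures. The threshold was 0.05 throughout. Correlations across sites of log2(S/N) with distance from the replication origin were Spearman's and Pearson's, each with a permutation p. The origin was placed between mnmG and mioC.

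Sites and genes named in the text follow a rule fixed before the data were examined. It takes the 15 sites with the highest S/N, up to 4 members with a site (highest S/N first) and up to 4 members without one (in alphabetical order) for each list, sites at rpoS, rpoD, rssB and crl, and the 3 widest sites. Any other gene named was chosen after its value was seen, and is named as such.

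Alternatives fixed in advance were the 1470 sites of highest S/N, merging of sites within 100 or 300 bp, placement by at least 50% of a site's length, windows of 150 bp outside to 50 bp inside and of 500 bp outside to 100 bp inside a gene's ends, a background of genes with at least 50 bp free at an end (in place of 50 bp upstream), the mean in place of the median, sites assigned to 1 gene only, and 10 bins in place of 20. Alternatives chosen after seeing the data were the 294 sites of highest S/N, an S/N of at least 1, genes bordering the gap that holds the site, rotations that set list members against other genes, the strongest site of each group within 300 bp, and leaving out the first 1160 kb of the coordinates. A promoter motif test was planned but needs the genome sequence, which was not used here. Tests on the authors' own site categories were planned, and the columns used here hold no categories.

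The tests were first tried on 20 simulated lists of 2941 sites placed uniformly. Of 300 Fisher tests without a planted effect, 5.3% had a p under 0.05. Uniform placement does not copy the excess of sites between genes in the real list, so this rate need not hold there. A site planted beside every known RpoS-dependent gene gave an adjusted p under 0.05 in 20 of 20 simulations by Fisher's exact test, and a p under 0.05 in 20 of 20 by rotation, against 0 of 20 by rotation without planting. Moving 10% of the sites between genes was called by rotation in 20 of 20 simulations and uniform sites in 0 of 20. A log2 shift of 1 in 100 sites was called in 20 of 20 simulations, and no shift in 0 of 20. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.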

Results

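RpoS, the general stress sigma factor of E. coli, directs RNA polymerase to promoters used in stationary phase and under stress. Its binding was mapped by ChIP-exo in wild-type MG1655 cells in mid-exponential phase in glucose minimal medium, a condition in which RpoS is usually scarce. The samples form 1 group of 2 biological replicates, and the deposited table holds 1 list of sites with 1 S/N value each and no replicate column. The questions this design allows are where RpoS was bound during growth, how strong the signal was there, and which groups of genes carried it. Depth per replicate is unknown from the table, no value carries a replicate error, and no other condition was there to compare with.

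The strongest sites included some beside a glycolytic gene and outer membrane protein genes and one in an acid resistance regulator. The highest S/N, 141, was between gapC, a disrupted copy of a glyceraldehyde-3-phosphate dehydrogenase gene, and cybB, which encodes cytochrome b561 (NC_000913.3, 1490720 to 1490772). The next were 133 between yggE and argO, the arginine exporter gene (3068097 to 3068151), and 120 between msrB and gapA, the glycolytic glyceraldehyde-3-phosphate dehydrogenase gene (1862510 to 1862562). A site with an S/N of 105 lay between ompA, encoding a major outer membrane protein, and sulA, the SOS inhibitor of cell division (1020152 to 1020204). Inside genes, the strongest sites were 72.8 in bcsE, a cellulose synthesis gene (3696723 to 3696775), 70.1 in gadX, an activator of acid resistance (3665764 to 3665818), and 52.4 in the overlapping small RNA genes ryeA and sdsR (1923162 to 1923215).

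The rest of the 15 strongest sites were all between genes. They lay between ycgB and dadA (S/N 93.3, 1237252 to 1237303), between insB4 and the cold shock family gene cspH (87.1, 1050667 to 1050720), and between glcA and the malate synthase gene glcB (76.5, 3121559 to 3121613). Further sites were between btsS and mlrA, an activator of the curli regulator gene (62.9, 2214824 to 2214876), and between the copper exporter gene copA and the glutaminase gene glsA (62.1, 511563 to 511615). A site of 59.1 ended at the first base of lpp, the gene of the major outer membrane lipoprotein, on the side of pykF (1757372 to 1757421). The last of these were between endA and rsmE (56.9, 3091042 to 3091096) and between yhjY and tag (54.3, 3712970 to 3713022). The sites next to insB4, an insertion sequence gene, and in the overlapping RNA genes were assigned by position only.

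The list held 2941 sites. Their median S/N was 1.62, with an interquartile range of 0.915 to 3.49 and extremes of 0.247 and 141. The S/N was under 1 at 843 sites (28.7%, Wilson 95% interval 27.1 to 30.3%) and 10 or more at 226 sites (7.68%). The 294 sites of highest S/N, all at 8.41 or above, held 51.6% of the summed S/N. Sites were narrow and of nearly 1 size, from 41 to 58 bp with a median of 50 bp, and together covered 149007 bp, or 3.21% of the chromosome. The widest were 58 bp inside yabP (S/N 2.91, 58686 to 58743), 57 bp between maeB and the transaldolase gene talA (14.9, 2578560 to 2578616), and 55 bp at yggE and argO, the strongest of 34 sites of that width. Merging sites within 100 bp left 2610 and merging within 300 bp left 2181.

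**Figure D1:**
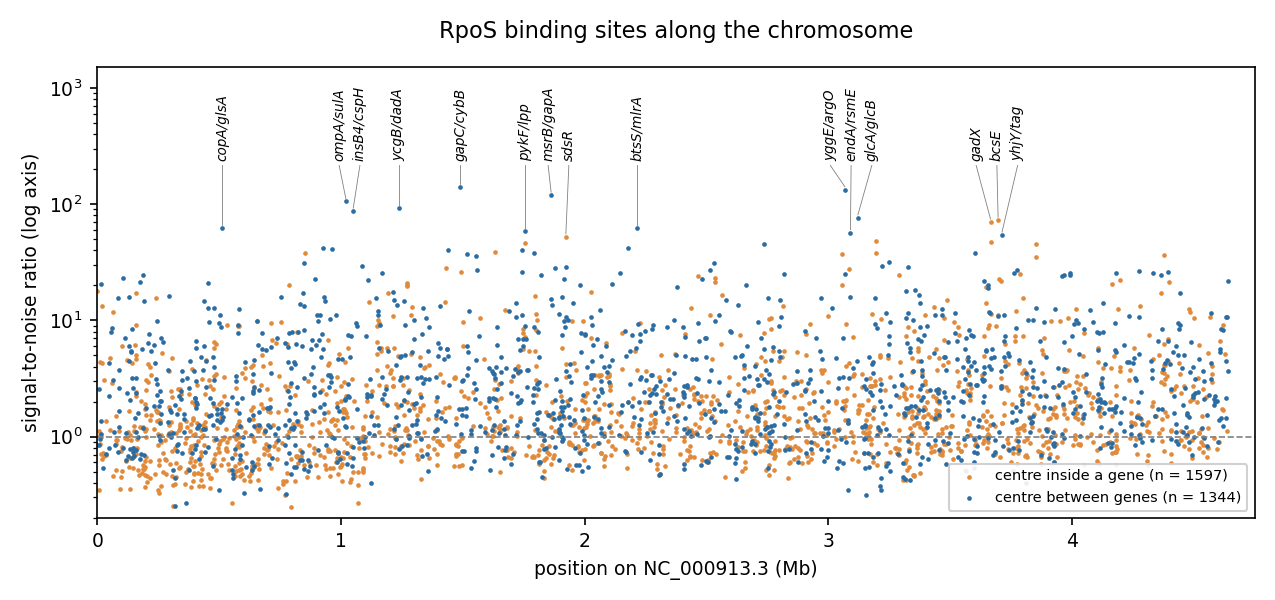
Each point is 1 RpoS binding site, at its position in Mb on NC_000913.3 (x axis) and its deposited S/N (y axis, log scale), blue for the 1344 sites centred between genes and orange for the 1597 centred inside a gene. The dashed line marks an S/N of 1, and the names are those of the genes at or beside the 15 strongest sites, from 52.4 at sdsR to 141 between gapC and cybB.

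RpoS sites lay between genes far more often than their number and spacing alone would give. Among sites between genes were those at gapA, ompA, mlrA and lpp, and 12 of the 15 strongest sites lay there. In all, 1344 of the 2941 sites (45.7%, Wilson 95% interval 43.9 to 47.5%) were centred between genes. Rotating the site set around the chromosome placed a mean of 10.7% there, with a range of 8.70 to 13.0% over 10000 rotations (two-sided permutation p = 0.0002, the smallest these rotations can give). The share was 31.2% among the weakest 295 sites and 65.6% among the strongest 294. Sites with an S/N under 1 were also above their rotations, with 268 of 843 between genes (31.8%, interval 28.7 to 35.01%) against a rotation mean of 10.7% and a maximum of 14.9% (permutation p = 0.0002).

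Sites between genes were also stronger than sites inside genes. The median S/N was 2.20 at the 1344 sites between genes and 1.28 at the 1597 inside them, a log2 difference of 0.78 (bootstrap 95% interval 0.65 to 0.92, permutation p = 1e-05, the smallest possible). Of 1448 sites inside a single protein-coding gene, 529 (36.5%) lay within 100 bp of one of its ends, where uniform placement in the same genes would give 25.7%. The gene table has no strand, so the 5′ and 3′ ends of genes could not be told apart.

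**Figure D2:**
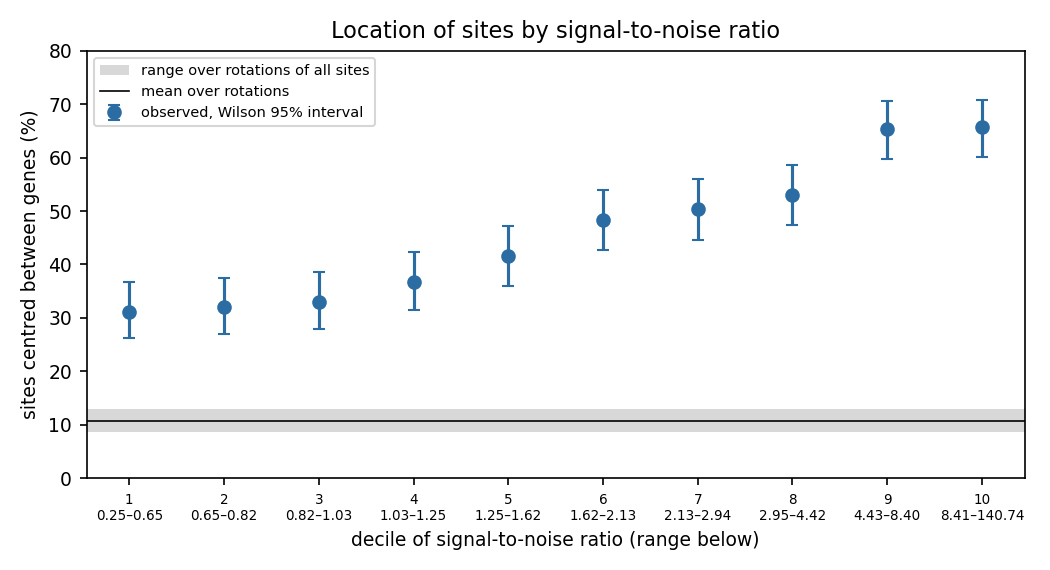
Points give the percentage of RpoS sites centred between genes (y axis) in each decile of S/N (x axis, with the S/N range of each decile), with Wilson 95% intervals as bars. The grey band is the range and the black line the mean of the same percentage over rotations of all sites, and every decile, from 31.2% in the weakest to 65.6% in the strongest, lies above the band.

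Genes known to depend on RpoS carried sites more often than other genes, and their sites were stronger. The highest values among them were at gadX (S/N 70.1), mlrA (62.9), fbaB, encoding the class I fructose-bisphosphate aldolase (42.0, at 2178595 to 2178646), and cfa, encoding cyclopropane fatty acid synthase (40.2, at 1741200 to 1741253). A site lay in the window of 67 of the 77 listed genes (87.0%) and of 59.1% of all other genes, an odds ratio of 4.63 (Fisher's exact test, adjusted p = 3.23e-06). The strongest site reached an S/N of 10 or more at 28 of the 67 and stayed under 1 at 5. The 10 members without a site included gabD, gadC, hdeB and hyaA, of which gadC and hdeB lie downstream in the gadBC and hdeAB operons.

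The 106 sites at known RpoS-dependent genes had a median S/N of 4.74 (interquartile range 1.81 to 11.2), against 1.58 at the other 2835 sites. The ratio of medians was 3.01 (bootstrap 95% interval 1.92 to 4.11), and the log2 difference of 1.59 had an adjusted permutation p of 0.00014. The other sites include the 672 assigned to no gene, and sites inside genes were weaker (median 1.28) than sites between genes (2.20). Position was not matched, so part of the difference, at this list and at the others, may reflect where the sites lie. The median of 4.74 was also above that of all sites between genes. The list was taken from general knowledge of the RpoS regulon, largely gathered in stationary phase or under stress. Of all annotated genes, 2771 of 4651 (59.6%) had a site, so the presence of a site separates genes only in part.

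**Figure D3:**
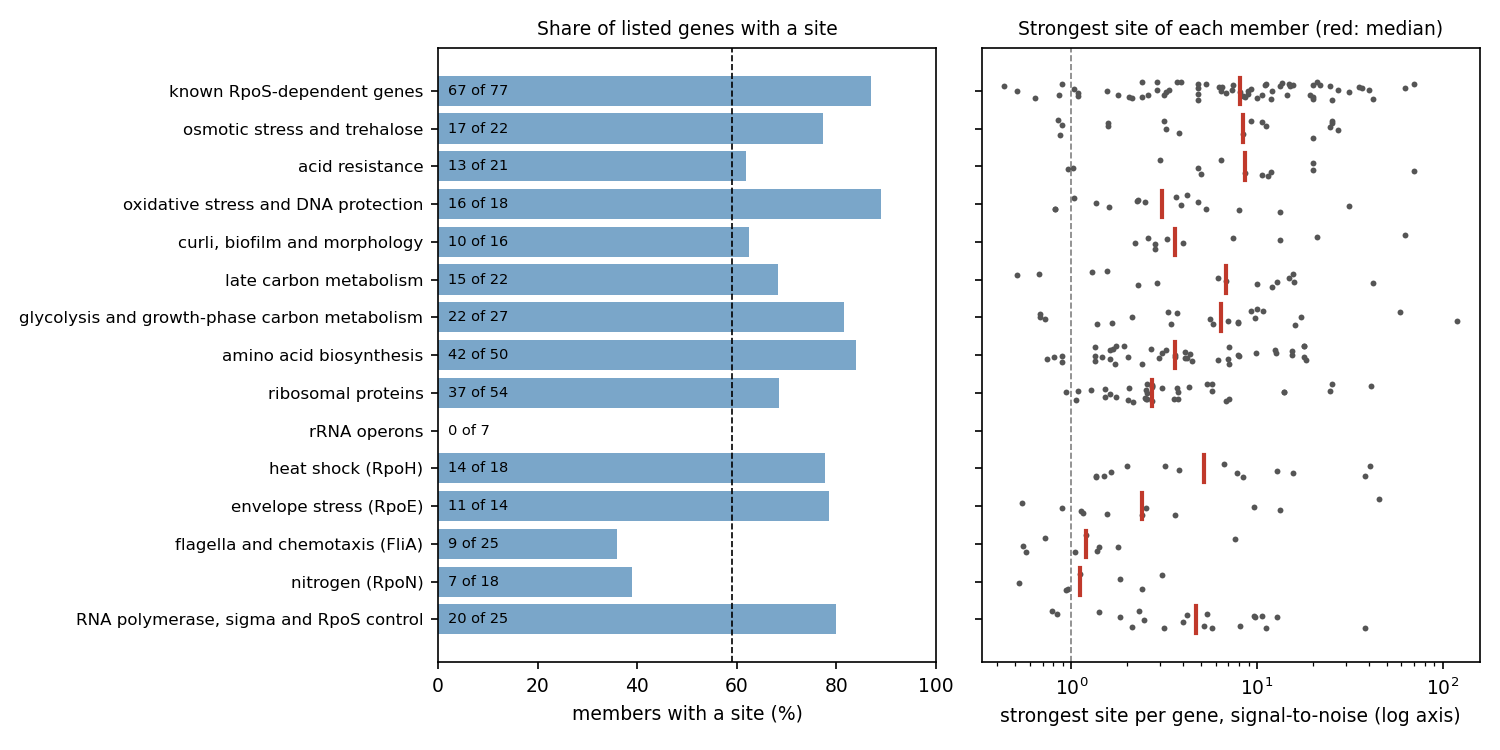
Bars (left, x axis in percent) give the share of each list's genes with an RpoS site within 300 bp outside to 100 bp inside an end, with the counts written in the bars and the share among genes outside the known RpoS-dependent list, 59.1%, as a dashed line. Points (right, x axis S/N on a log scale) give the strongest site of each member with a site, red lines their median and the dashed line an S/N of 1, and the medians run from 1.11 for the nitrogen list to 8.58 for acid resistance.

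Osmotic stress genes carried strong sites at osmC, encoding an osmotically inducible peroxidase (S/N 27.2), the osmoprotectant transporter gene proP (25.3), the mechanosensitive channel gene mscS (25.2) and osmE (24.8). Sites lay at 17 of the 22 members, an odds ratio of 2.31 that did not pass the test (Fisher's exact test, adjusted p = 0.21). The odds ratio was 6.11 with the 294 strongest sites (Fisher's exact test, adjusted p = 0.00134) and 3.79 for genes bordering the gap that holds a site (adjusted p = 0.0197). The members without a site included otsA, the trehalose-6-phosphate synthase gene, proW and proX of the proVWX operon, and yehX. The 24 sites had a median S/N of 3.49 against 1.61 elsewhere (log2 difference 1.11, adjusted permutation p = 0.0102), although the bootstrap interval of -0.18 to 2.52 included 0. With only the strongest site of each group within 300 bp, the log2 difference was 0.98 and the adjusted p 0.0569.

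Of the oxidative stress and DNA protection genes, dps, encoding the DNA-binding protein of starved cells, had the strongest site (S/N 31.3, at 848914 to 848968). It was followed by the redox-sensing regulator gene soxR (13.3), the superoxide dismutase gene sodA (7.99) and aidB (5.31), while ahpF and soxS had none. The site credited to soxR lies 127 bp outside it, inside the small RNA gene ryjA, and its assignment to soxR rests on the window alone. The count was 16 of 18 members, an odds ratio of 5.45 that did not pass the test (Fisher's exact test, adjusted p = 0.0514), nor did the median S/N of 2.30 against 1.61 (log2 difference 0.51, adjusted permutation p = 0.27). With the window of 150 bp outside to 50 bp inside gene ends, the odds ratio was 8.79 with an adjusted p of 0.0024, and it also passed with an S/N of at least 1 (3.65, Fisher's exact test, adjusted p = 0.0369) and outside the first 1160 kb of the coordinates (8.82, adjusted p = 0.0394). It was 2.46 among the 1470 sites of highest S/N (Fisher's exact test, adjusted p = 0.119), 3.91 against genes with at least 50 bp free at an end (adjusted p = 0.124) and 1.09 with the 294 strongest sites (adjusted p = 0.817).

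Several of the acid resistance genes with a site lie between slp and gadA. Besides gadX, strong sites lay at hdeA, the periplasmic acid chaperone gene, and hdeD, which share a site with an S/N of 20.1 (3656752 to 3656804), and at gadE, the central activator of glutamate-dependent acid resistance (11.9, 3658236 to 3658288). The adi genes of arginine-dependent acid resistance, adiA, adiC and adiY, and cadB of lysine-dependent resistance had no site. Sites lay at 13 of the 21 members (61.9%, against 59.6% of other genes), which did not pass the test (odds ratio 1.10, Fisher's exact test, adjusted p = 1). With the 294 strongest sites the odds ratio was 4.39 (7 of 21 members, Fisher's exact test, adjusted p = 0.0154). The sites present had a higher median S/N than others, 5.68 over 18 sites against 1.61 (log2 difference 1.82, interval 0.87 to 2.87, adjusted permutation p = 0.00126). The strongest site reached an S/N of 10 or more at 6 of the 13 members and stayed under 1 at 1. The glutamate decarboxylase genes gadA and gadB are near-identical copies, so their own sites are uncertain.

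**Figure D4:**
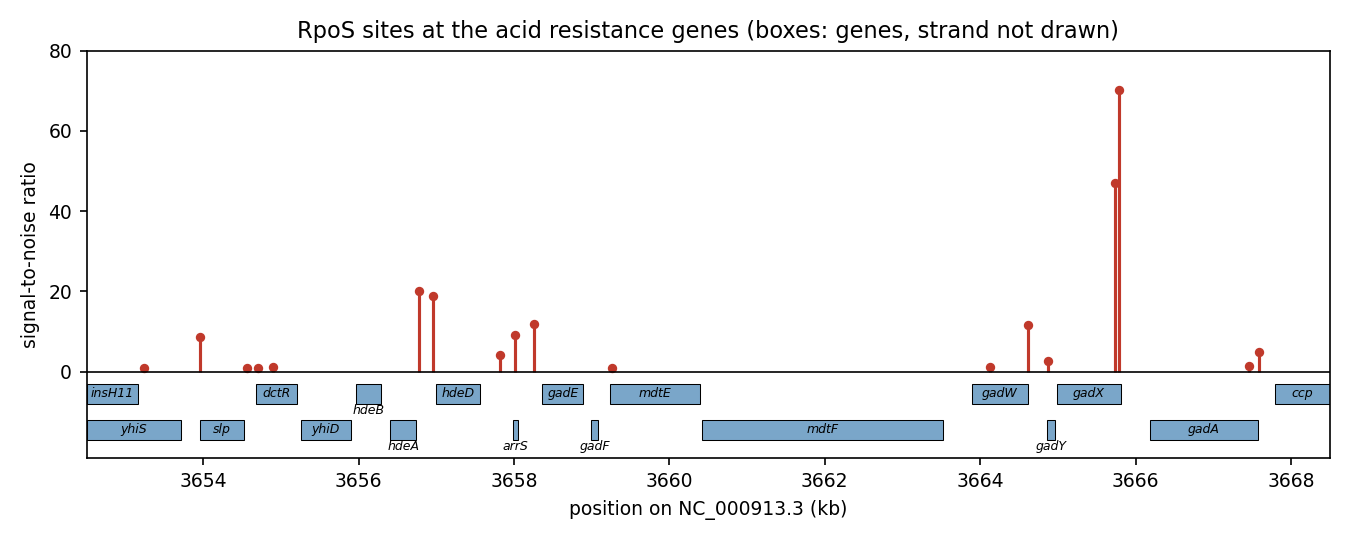
Vertical lines with points mark RpoS sites at their position in kb on NC_000913.3 (x axis) with their deposited S/N as height (y axis, linear), over boxes for the annotated genes of the region between insH11 and ccp, in which box height and level carry no meaning. The tallest site, 70.1, lies at the end of gadX nearest gadA, and the sites between hdeA and hdeD reach 20.1.

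Among curli, biofilm and morphology genes, sites lay at mlrA (S/N 62.9), at the morphology gene bolA (20.95), at dgcM (13.3), which encodes a diguanylate cyclase, and at csgD, the curli regulator gene (7.40). The cellulose synthase genes bcsA and bcsB and the curli export genes csgE and csgF had none. The count of 10 of 16 did not pass the test (odds ratio 1.13, Fisher's exact test, adjusted p = 1), and the median S/N of 2.81 at 15 sites against 1.61 did not pass the test (log2 difference 0.80, adjusted permutation p = 0.125). The bootstrap interval of that difference, 0.40 to 2.16, excluded 0. With means in place of medians, the log2 difference was 1.01 with an adjusted p of 0.0137. With medians it was 0.047 among the 1470 sites of highest S/N (adjusted permutation p = 0.926) and 0.42 with an S/N of at least 1 (adjusted permutation p = 0.512).

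Late carbon metabolism was represented by fbaB (S/N 42.0), the succinate dehydrogenase gene sdhC (15.8), the glycogen-related gene glgS (15.7) and talA (14.9), with no site at aceA, fumC, gabD or gabP. Sites lay at 15 of 22 members (odds ratio 1.46, Fisher's exact test, adjusted p = 0.595). The odds ratio was 4.10 with the 294 strongest sites (Fisher's exact test, adjusted p = 0.0154). The median S/N of 2.91 at 23 sites against 1.61 gave a log2 difference of 0.85 (bootstrap interval 0.15 to 2.57, adjusted permutation p = 0.051). Among the 1470 sites of highest S/N that difference was 1.31 with an adjusted p of 0.00882, and outside the first 1160 kb of the coordinates it was 0.69 with an adjusted p of 0.126. It also passed the permutation test with means (1.03, adjusted p = 0.00294), with the strongest site of each group within 300 bp (1.86, adjusted p = 0.00133) and with an S/N of at least 1 (1.41, adjusted p = 0.00233). The bootstrap interval included 0 among the 1470 sites (-0.23 to 1.92) and with an S/N of at least 1 (-0.21 to 2.18). It also included 0 outside the first 1160 kb (-0.03 to 2.46). It excluded 0 with means (0.36 to 1.71) and with the strongest site of each group within 300 bp (0.16 to 2.77).

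Genes of growth-phase carbon metabolism also carried strong sites. They were led by gapA (S/N 120), pykF, encoding pyruvate kinase I (59.1), icd, encoding isocitrate dehydrogenase (17.3), and acnB, encoding aconitase B (15.9), while aceE, fbaA, ptsI and rpe had none. The site credited to pykF lies at the first base of lpp, and its assignment to pykF rests on the window alone. Sites lay at 22 of 27 members, an odds ratio of 3.001 that did not pass the test (Fisher's exact test, adjusted p = 0.0712). The 39 sites had a median S/N of 3.51 against 1.61 (log2 difference 1.13, interval 0.36 to 1.85, adjusted permutation p = 0.00149). Among the 1470 sites of highest S/N the odds ratio was 3.15 with an adjusted p of 0.0142, and it also passed for genes bordering the gap that holds a site (4.98, Fisher's exact test, adjusted p = 0.00173), with the window of 500 bp outside (6.24, adjusted p = 0.0181), with the 294 strongest sites (3.70, adjusted p = 0.0154) and with an S/N of at least 1 (2.48, adjusted p = 0.049). With the window of 150 bp outside to 50 bp inside gene ends it was 1.59 with an adjusted p of 0.373.

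Amino acid biosynthesis genes carried sites more often than other genes, and at 8 of them the strongest reached an S/N of 10 or more. The highest were at gltB, encoding the large subunit of glutamate synthase (S/N 18.4), argG (18.0), and the threonine leader and first structural gene thrL and thrA, which share a site of 17.8. No site was found at argC, argE, aroH or asnB. Sites lay at 42 of 50 members (84.0%), an odds ratio of 3.601 (Fisher's exact test, adjusted p = 0.00181), and their median S/N of 1.77 at 61 sites against 1.61 elsewhere did not pass the test (log2 difference 0.13, interval -0.09 to 0.70, adjusted permutation p = 0.557). Against genes with at least 50 bp free at an end, the odds ratio was 2.52 and the adjusted p 0.0678. It was 1.67 for genes bordering the gap that holds a site and 1.92 with the 294 strongest sites, both with an adjusted p of 0.178, and past the threshold in the other settings.

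Ribosomal protein genes had sites at 37 of 54 members, with the highest S/N at rpsA (41.1), rplA (25.5), rpsB (24.7) and rpsI (14.02) and none at rplC, rplD, rplF or rplO. The odds ratio was 1.48 (Fisher's exact test, adjusted p = 0.262), and the median S/N was 2.22 at 56 sites against 1.61 (log2 difference 0.47, adjusted permutation p = 0.101). The bootstrap interval of that difference, 0.03 to 0.75, excluded 0. With the 1470 sites of highest S/N the odds ratio was 1.97 with an adjusted p of 0.0408, with an S/N of at least 1 it was 2.09 with an adjusted p of 0.0369, with the window of 500 bp outside the adjusted p was 0.0214, and with the 294 strongest sites it was 0.886 with an adjusted p of 1. The 16S rRNA genes, by contrast, had no site at any of 7 members, among them rrsA, rrsB, rrsC and rrsD (Fisher's exact test, adjusted p = 0.00876). In rotations that set the list against other genes, the adjusted permutation p was 0.003. That p carries no weight, since 59.7% of other genes had a site against a mean of 37.6% of all genes over rotations. A list with a count of 0 then lies beyond the rotations by construction. Against random placement alone, which gives 2.66 of the 7, the adjusted permutation p was 0.101. Among the 1470 sites of highest S/N the adjusted p was 0.102. With the window of 500 bp outside, 1 of the 7 had a site (Fisher's exact test, adjusted p = 0.0199). For genes bordering the gap that holds a site it was also 1 of the 7, and the call was lost (odds ratio 0.235, Fisher's exact test, adjusted p = 0.418). These genes are near-identical copies.

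Of the lists named for other sigma factors, only the heat shock list passed a test in the main settings, that of signal. In the heat shock (RpoH) list, sites lay at 14 of 18 members, with the highest S/N at hslJ (40.5), at rpoH itself (38.2), at the chaperone cofactor gene grpE (15.6) and at the protease gene clpP (12.8), and none at hslO, hslR, htpG or ibpB. Its odds ratio of 2.38 did not pass the test (Fisher's exact test, adjusted p = 0.224), and its 21 sites had a median S/N of 3.21 against 1.61 (log2 difference 0.99, interval -0.04 to 2.28, adjusted permutation p = 0.0305). With sites of S/N at least 1 the log2 difference was 0.64 and the adjusted p 0.146, and among the 1470 sites of highest S/N they were 0.92 and 0.0555. The presence of sites passed with the window of 500 bp outside (odds ratio 8.47, Fisher's exact test, adjusted p = 0.0228) and with an S/N of at least 1 (3.65, adjusted p = 0.0369). In the envelope stress (RpoE) list, 11 of 14 had a site, led by bamD (45.5), the small RNA gene micA (13.2), rpoE (9.66) and sbmA (3.63), and degP, dsbC and rybB had none. Neither its odds ratio of 2.49 (Fisher's exact test, adjusted p = 0.245) nor its median S/N of 2.29 passed a test (log2 difference 0.50, adjusted permutation p = 0.31).

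The lists named flagella and chemotaxis (FliA) and nitrogen (RpoN) had the lowest values of the lists with sites. Not every member of the RpoN list is a gene of nitrogen metabolism, and not every member of the FliA list need depend on FliA. In the flagella and chemotaxis (FliA) list 9 of 25 members had a site, with S/N of 7.64 at fliZ, 1.78 at aer, 1.42 at fliA and 1.38 at fliE, and cheA, cheW, flgA and flgB had none. The odds ratio of 0.380 did not pass the test (Fisher's exact test, adjusted p = 0.0685), and neither did the median S/N of 1.12 against 1.62 (log2 difference -0.53, adjusted permutation p = 0.31). The bootstrap interval of that difference, -1.32 to -0.03, excluded 0. In the nitrogen (RpoN) list 7 of 18 had a site, at most 3.08 at prpB, 2.41 at glnA, 1.83 at argT and 1.11 at hisJ, with none at atoD, ddpX, fdhF or glnK. Its odds ratio was 0.430 (Fisher's exact test, adjusted p = 0.172) and its median S/N 1.03 (log2 difference -0.65, adjusted permutation p = 0.31). With the window of 150 bp outside to 50 bp inside gene ends, the odds ratios were 0.271 and 0.217, both with an adjusted p of 0.0252. Both lists also passed with the window of 500 bp outside (0.388 and 0.314, Fisher's exact test, both with an adjusted p of 0.0344) and with an S/N of at least 1 (0.326 and 0.295, adjusted p = 0.0369 and 0.049). In rotations that set each list against other genes the adjusted permutation p was 0.092 and 0.163, and for genes bordering the gap that holds a site the RpoN odds ratio was 0.898 (Fisher's exact test, adjusted p = 1).

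The genes that make and control RNA polymerase were bound at several regulators of RpoS. Besides rpoH (S/N 38.2) and clpP (12.8), whose product is part of the protease that degrades RpoS, sites lay at rssA (11.2) and at dsrA, the gene of a small RNA that promotes rpoS translation (10.7). At rssB, encoding the adaptor that delivers RpoS to that protease, a site of 5.35 lay 42 bp outside the gene on the side of rssA (1290175 to 1290224). At crl, whose product assists RpoS in binding core polymerase, sites of 2.46 and 1.37 lay 14 bp outside and within the gene (257790 to 257839 and 258795 to 258844). The gene rpoS itself (b2741, 2866559 to 2867551) had no site in the window. The nearest lay 559 bp outside it, inside nlpD, the neighbouring gene that holds the main rpoS promoter (2.88, 2868085 to 2868136).

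The housekeeping sigma factor gene rpoD also had no site in the window. The nearest were 344 and 452 bp outside it, inside dnaG (S/N 1.09, 3212678 to 3212727, and 3.12, 3212570 to 3212619). The list's other members without a site were iraM, nlpD and rpoN. In all, 20 of 25 members had a site, an odds ratio of 2.73 that did not pass the test (Fisher's exact test, adjusted p = 0.0876), and the 30 sites had a median S/N of 3.41 against 1.61 (log2 difference 1.08, interval 0.29 to 1.72, adjusted permutation p = 0.00591). The presence of sites passed among the 1470 sites of highest S/N (odds ratio 3.34, Fisher's exact test, adjusted p = 0.0139), with the window of 500 bp outside (5.74, adjusted p = 0.0192) and with an S/N of at least 1 (2.68, adjusted p = 0.049). For signal, by the same permutation test, the log2 difference was -0.05 with the 3 sites assigned to 1 gene only (adjusted permutation p = 0.963) and 0.58 among the 1470 sites of highest S/N (adjusted permutation p = 0.124).

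Along the chromosome, sites were spread over all 20 bins of 232 kb, with 105 to 189 sites and a median S/N of 1.12 to 2.36 per bin. The region around the origin, between mnmG and mioC, did not stand out, with 1489 sites and a median S/N of 1.67 on the side of the chromosome nearest the origin and 1452 sites and 1.59 on the side nearest the terminus. Across sites, log2(S/N) showed no correlation with distance from the origin that passed the test (Spearman's rho = -0.0346, permutation p = 0.0621, Pearson's r = -0.0228, permutation p = 0.22). After adjustment over 4 correlations these p-values were 0.248 and 0.44. Among the 1470 sites of highest S/N, rho was 0.00521 (permutation p = 0.843) and r 0.0173 (permutation p = 0.508).

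The share of weak sites was uneven. In the first 1160 kb of the coordinates, from thrL onwards, 333 of 841 sites (39.6%, Wilson 95% interval 36.3 to 42.9%) had an S/N under 1, against 510 of 2100 (24.3%, interval 22.5 to 26.2%) in the rest (Fisher's exact test, p = 4.61e-16). This comparison was chosen after the values per bin were seen. Sites with an S/N of 10 or more numbered 45 in that part, and 61, 57 and 63 in the following stretches of the same length. Sites with an S/N of 1 or more numbered 508, and 523, 539 and 528 in those stretches. Sites under 1 numbered 333, and 163, 199 and 148 there, so the part differed mainly in holding more weak sites.

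**Figure D5:**
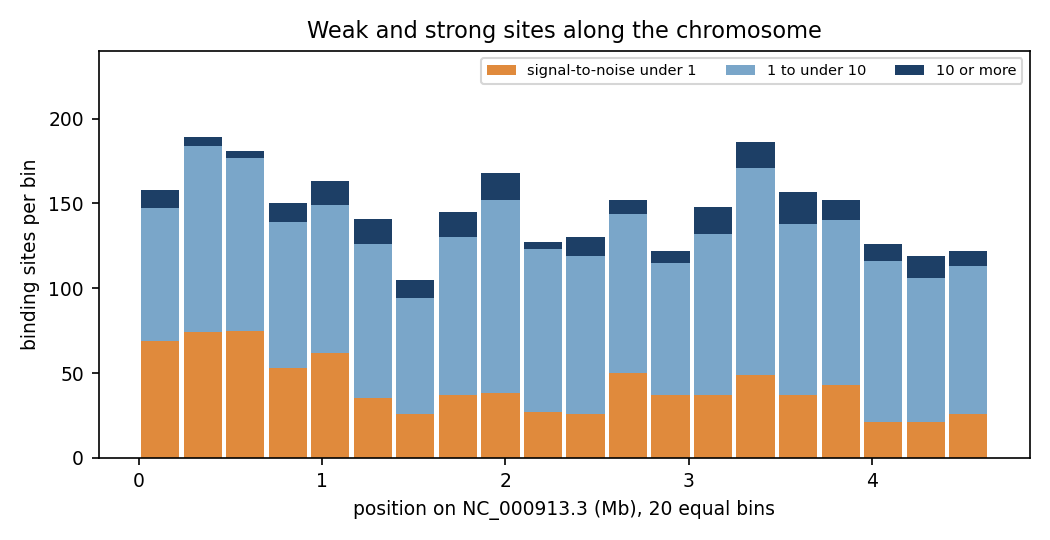
Stacked bars give the number of RpoS sites (y axis) in each of 20 equal bins along NC_000913.3 (x axis, Mb), split into sites with an S/N under 1 (orange), from 1 to under 10 (light blue) and 10 or more (dark blue). The orange part is tallest in the first bins, where 39.6% of the sites of the first 1160 kb are under 1, against 24.3% in the rest.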

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

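The settings that use the 294 strongest sites, an S/N of at least 1, genes bordering a gap, rotations of members against other genes, the strongest site per 300 bp, or all but the first 1160 kb were chosen after the data were seen, and the others before. The share of sites between genes stayed above its rotations in 5 of 5 alternatives, from 45.4 to 65.6%. The known RpoS-dependent genes stayed past the threshold in 9 of 9 settings for the presence of sites, with odds ratios (or, for rotation, a ratio of members to other genes) from 1.46 to 6.92 and an adjusted p of at most 0.003. In 6 of 6 settings for signal, their log2 differences were 1.05 to 2.46 with an adjusted p of at most 0.000765, but the highest, from 11 sites assigned to 1 gene only, had a bootstrap interval of -0.65 to 4.08. The settings with the sites of highest S/N and with an S/N of at least 1 select sites on the value compared, so they are not independent checks. No setting for signal matched sites by their position between or inside genes.

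Keeping the sites of highest S/N leaves 1470 of 2941 by construction. The number of lists past the threshold for the presence of sites was 3. It was 2 against genes with 50 bp free, 3 for genes bordering a gap, 3 by rotation and 4 without the first 1160 kb, and rose to 6 with those 1470 sites, 6 with the 150 bp window, 9 with the 500 bp window, 5 with the 294 strongest sites and 10 with an S/N of at least 1. The cause of these changes was not tested. The 3 by rotation include the rRNA list, whose p there is fixed by its count of 0 members. Over the lists and settings, 27 values for the presence of sites passed the threshold where the reported one did not and 6 lost it. For signal 5 passed and 4 lost it, among them the RpoS control list with the 1470 sites of highest S/N. The value of that list with sites assigned to 1 gene only is not counted here and is given below.

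The following values lie on the opposite side of no difference from the reported value, and neither that value nor these passed the test. For the presence of sites, acid resistance had an odds ratio of 0.992 with the 500 bp window and 0.790 against genes with 50 bp free, ribosomal proteins 0.886 with the 294 strongest sites, and RpoE genes 0.564 for genes bordering a gap. For signal, the log2 difference was -0.18 for ribosomal proteins and 1.11 for FliA genes (3 sites) with the 1470 sites, -0.65 for oxidative stress genes with sites assigned to 1 gene only (3 sites), and -0.17 for amino acid genes with an S/N of at least 1. The exception is the RpoS control list, which passed as reported and had -0.048 with sites assigned to 1 gene only, from 3 sites, too few to show by themselves that the call depends on processing. The call was also lost among the 1470 sites of highest S/N, from 21 sites (log2 difference 0.58, adjusted permutation p = 0.124). That setting selects sites on the value compared, so this loss does not by itself show that the call depends on processing. The call held with means, with the strongest site of each group within 300 bp, with an S/N of at least 1 and outside the first 1160 kb. The correlation with distance from the origin was 0.00521 with the 1470 sites. The cause was not tested. No paired analysis was possible because the table has no replicate columns and the series has 1 group, and for the same reason leaving out a replicate and the 50 and 200 bp criteria for shared sites were not run. The motif alternatives and those on the authors' categories were not run either. Depth per sample is unknown, so what it limits cannot be stated.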

Other observations

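All tests in this part were chosen after the results were seen, except that on insertion sequence genes, which was written down before its result was known. The test of whether growth-phase sites belong to listed neighbours was restated after a first version, which removed shared sites, had turned out to have none to remove. Genes named in this part were chosen after their values were seen.

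Small RNA genes carried RpoS sites often, and the sites inside them were strong. After the overlapping ryeA and sdsR genes (S/N 52.4), sdsR being a small RNA known to depend on RpoS, the highest were sibD (48.1), istR, the antitoxin RNA of the tisB toxin gene (45.5), rybA (38.3), sibE (38.0), sibC (37.5) and sokB (25.8). A site lay at 78 of 107 small RNA genes (72.9%) and at 2582 of 4290 protein-coding genes (60.2%), an odds ratio of 1.78 (Fisher's exact test, adjusted p = 0.0134 over 3 gene types). The 59 sites inside small RNA genes had a median S/N of 4.23 against 1.60 elsewhere (log2 difference 1.40, interval 0.76 to 2.34, adjusted permutation p = 3e-05). The other sites include 1460 inside protein-coding genes, with a median of 1.23, and 1344 between genes, with a median of 2.20. The difference from sites between genes is therefore smaller. Transfer RNA genes had a site less often, at 30 of 86 (odds ratio 0.354, adjusted p = 1.05e-05), but the 16 sites inside them were strong, with a median of 4.0004 (log2 difference 1.30, adjusted permutation p = 0.00829). Pseudogenes did not pass either test (odds ratio 0.770, adjusted p = 0.143, log2 difference -0.37, adjusted permutation p = 0.0976). The sib and rdl genes are families of similar copies, so sites in them are uncertain. The transfer RNA gene gltV lies between rrsE and rrlE in a stretch without a site. Loss of sites in repeated sequence, taken up below, may therefore also lower the share of transfer RNA genes with a site. Genes this short also have a smaller window in all than longer genes. Neither was tested for the transfer RNA genes.

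Long stretches without a site were more frequent than uniform placement gives. The longest, of 16602 bp (1445521 to 1462122), ran from ynbE through the phenylacetate degradation genes to paaJ, and the next, of 16470 bp, held puuB, pspA and ycjM. Others spanned the threonine degradation genes around tdcB (16150 bp), the hydrogenase genes hyfA to hyfJ (15884 bp) and the nitrite reductase genes around nrfA (14816 bp). There were 14 stretches of 12 kb or more, where 1000 uniform placements of as many sites gave a mean of 1.42 and a 97.5th percentile of 4. The longest stretch itself lay within what these placements gave, with a mean longest stretch of 13493 bp and a 97.5th percentile of 18620 bp. Uniform placement also ignores that sites cluster. There were 331 neighbouring sites under 100 bp apart, against a mean of 267 and a 97.5th percentile of 297 in these placements. Clustering can leave more long stretches. Whether it accounts for the 14 was not tested, so the excess is not read as a result about the genes in them.

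No site was found from 300 bp outside to 100 bp inside an end of any of the 7 16S rRNA genes, nor inside any of the 22 rRNA genes, whose 32083 bp would hold 11.9 sites at the density of other protein-coding genes (exact binomial p = 1.29e-05). Reads shared between near-identical copies are a candidate explanation, and the insertion sequence genes, which are also near-identical copies, bear on it. The 58 genes of the multi-copy families held 1 site in 38171 bp where 14.1 would match that density, a ratio of 0.0708 (exact binomial p = 2.12e-05). This is in line with a loss of sites in repeated sequence, but insertion sequence genes may also be bound rarely for reasons of their own, so absence of RpoS from the rRNA operons stays open. With the window of 500 bp outside, 1 of the 7 had a site. No biological explanation was tested.

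Weak sites were more frequent in the first 1160 kb of the coordinates, at 39.6% against 24.3% in the rest. Gene dosage from the replication origin is argued against, since at the same distances from the origin the percentage with an S/N under 1 was 39.6% on the clockwise arm and 26.1% on the counterclockwise arm, a difference of 13.49 percentage points (Fisher's exact test, p = 3.17e-08). The clockwise arm here is the first 1160 kb itself, chosen after its values were seen, so this p overstates the evidence. Dosage would act on both arms alike, and the counterclockwise arm was near the 24.3% of the rest, of which it is part. Site calling that changed along the coordinate would put a step where the numbering begins, a point set by convention. The change across coordinate 1, from 21.3% in the last 232 kb to 43.7% in the first, was 22.4 percentage points, and 0.2151% of 465 positions, coordinate 1 alone, had a change as large. This restates the values per bin that led to the test, so it does not bear on the explanation, and a step in site calling and a real regional difference cannot be told apart. Leaving this part out moved the share of sites between genes to 46.9%. No biological explanation other than gene dosage was tested.

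Strong sites at both known RpoS-dependent genes and growth-phase carbon genes such as gapA raise the hypothesis that the signal follows transcription in general, for which ribosomal protein genes, among the most transcribed in growing cells, may serve as a gauge. Sites at known RpoS-dependent genes were stronger than those at ribosomal protein genes, by a log2 difference of 1.094 (106 and 56 sites, bootstrap 95% interval 0.40 to 1.67, permutation p = 0.00277). This does not decide the question, because the lists differ in layout. At least 50 bp was free at an end of 69 of 77 known genes but only 33 of 54 ribosomal protein genes. Sites between genes were stronger in general, so layout alone could lower the ribosomal protein median. The growth-phase carbon list minus the ribosomal protein list gave 0.66 (interval -0.15 to 1.499, permutation p = 0.081), which leaves open whether these lists differ. Sites that belong to listed RpoS-dependent neighbours are argued against, as 0 of the 39 growth-phase carbon sites also lay at a listed RpoS-dependent gene, although unlisted neighbours could still account for some. Binding of RpoS at promoters shared with the housekeeping sigma factor, and precipitation of other polymerase by the antibody, were not tested, and transcription was not measured here. No other biological explanation was tested.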
